A study of Carica papaya with 12 samples.

How the data were processed

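Total RNA from 1 g of ground papaya (Carica papaya) fruit was made into libraries with the TruSeq RNA kit, version 2, per the labels' protocols. The 12 libraries form 4 groups of 3, from genotypes CI-05 and CI-13 at 5 and 6 days post harvest. All fruit carried natural anthracnose, for which the labels name Colletotrichum gloeosporioides and Colletotrichum truncatum. No uninfected fruit was among the samples analysed here, and the labels state no sequencing batch. Nothing in the labels says whether the replicates of a group came from separate fruits, so the p-values measure only the spread between these samples, which may be technical.

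The values are estimated counts per identifier, deposited by the authors as 1 table of 24702 identifiers. They were made with Salmon 1.10.3, per the submitters' processing notes. The genome build, the annotation, the index and the options were not given in the sources used here. Each identifier is called a gene in the text. Without the annotation it was not checked whether an identifier stands for a gene or for a transcript. None of the 208485 values above 0 was exactly whole. Values between 0.75 and 1.25 had medians of 1.007 to 1.021 per library with SDs of 0.025 to 0.033, as if each gene had been rescaled slightly, and the sources used here do not say how. The counts were rounded to whole numbers before any test. The 113 identifiers with no value in any library were left out, and 3519 further identifiers were at 0 in every library. All 12 value columns were matched to samples by their descriptions.

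Identifiers were looked up in a RefSeq gene table of papaya with 48816 genes. The number that matched was 0, and the table of counts pairs its identifiers with no names. The lists of gene families and the tissue markers that had been fixed before the data were examined were therefore void. The camera and fry set tests planned for them were not run, and genes are given by identifier only. All identifiers share 1 prefix, so no fungal share of the counts could be taken.

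Library totals ran from 5773325 to 8158483 estimated counts. A count of 3 corresponded to 0.368 to 0.52 CPM, the unit of counts scaled to a common library total, in a single library. Over a group's 3 libraries, 3 counts corresponded to 0.13 CPM in CI-05 at 5 days, 0.191 in CI-05 at 6 days, 0.144 in CI-13 at 5 days and 0.156 in CI-13 at 6 days. Fold changes against a group at 0 in all libraries are given as lower bounds against this group limit. Where the lower group held 1 count, the ratio is that of the groups' summed counts, each divided by the sum of TMM-scaled library totals, with its exact 95% counting interval. It differs from the ratio of mean CPM. These limits and intervals cover counting error only, since they leave out the spread between libraries. The reads carried no molecular identifiers, so copies of the same molecule may have been counted more than once. Even the counting error may therefore be larger than given.

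Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, two-sided, with TMM factors and the filterByExpr filter. The filter kept 14664 genes. All 12 libraries entered 1 fit with a mean for each group and no covariate, which left 8 residual degrees of freedom. The common biological coefficient of variation was 25.3%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p in the text comes from this test unless another tool is named. Each SE of a log2 fold change is its absolute value divided by the square root of the F statistic. It is thus derived from the test and not a separate estimate. The comparisons were CI-13 against CI-05 at each day, 6 against 5 days in each genotype, and the interaction, which is the day effect in CI-13 minus that in CI-05. CPM values are TMM-scaled means ± SD over 3 libraries. Principal components were taken from log2 CPM with a prior count of 2. Overlaps of calls were set beside the number expected for independent lists, from comparisons that shared no library. That number takes every gene as equally likely to be called. The lists came from 1 fit with a shared spread per gene, so genes differ in this.

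On simulated counts with the real means and library sizes and 200 changed genes, the test recovered 35% of 2-fold and 67% of 4-fold changes for the genotype comparison at 5 days, with 14332 genes tested. For the change in CI-13 the shares were 36% and 66%, again of 14332 genes. With 14306 genes they were 32% and 62% for the genotypes at 6 days and 32% and 65% for the change in CI-05. For the interaction they were 7% and 41%. False calls made up 2% to 8.9% of the simulated calls. The simulation gave 51 interaction calls and the data 4814, and more calls make the adjusted threshold less strict. The simulated shares therefore do not give the share of changes missed in the data.

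The genes named in the text follow a rule fixed before the data were examined. Among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, the largest fold changes were taken. The rule asked for 6 genes per direction, and for 5 in the interaction. Without gene names it was reduced to 2 per direction in every comparison, and its part on gene lists was left out. The part of the rule on overlap did not apply to the interaction. Genes or classes chosen after their values were seen are marked as such.

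Alternatives fixed before the data were examined were median-of-ratios factors, DESeq2 1.42.0 with its Wald test, no low-count filter, a minimum mean count of 50, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Alternatives added after the data were seen were library totals alone, leaving out the 100 most abundant genes, thinning all libraries to the smallest, and summing neighbouring identifiers that mirrored each other. For the last, an identifier qualified if it was at 0 in 1 library and at 5 CPM or more in another of the same group. It was summed with the smallest set of identifiers within 2 numbers of it whose summed deviations from the group means correlated with its own at -0.8 or below and lowered the spread within groups. Sets that shared an identifier were joined. GWHTBFSC002171, GWHTBFSC002172 and GWHTBFSC002173 were also summed, a choice made by hand after their values were seen. Shares of the counts in CI-05 were tested against a 2-fold change between the days with edgeR's glmTreat, with library totals and no TMM factors. Tables and plots were made with pandas and matplotlib in Python.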

Results

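Messenger RNA was profiled in papaya fruit with natural anthracnose, a rot caused by Colletotrichum fungi, in genotypes CI-05 and CI-13 at 5 and 6 days post harvest. Each of the 4 groups held 3 libraries. The series title ties resistance to the timing of transcriptional responses, so the comparisons ask how the genotypes differed on each day and how each changed between the days. The labels do not say which genotype was the more resistant. Library totals ran from 5773325 to 8158483 estimated counts. The lowest and highest totals of a group were 6620924 and 8158483 in CI-05 at 5 days, 5899485 and 6507197 in CI-05 at 6 days, 5773325 and 6595980 in CI-13 at 5 days, and 6056234 and 6588169 in CI-13 at 6 days. Between 16811 and 17931 genes had a count of 1 or more in a library.

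CI-05 fruit at 6 days stood apart from all other fruit. The first principal component held 46.1% of the variance and placed the 3 CI-05 libraries of 6 days between 99.5 and 124.4, and the other 9 libraries between -70.2 and -19.4. The second component held 13.6% and placed CI-13 at 6 days highest, between 33.2 and 62. Correlations of log2 CPM across genes lay between 0.935 and 0.961 within groups. The genotypes correlated at a mean of 0.915 at 5 days and of 0.779 at 6 days. Within CI-05 the days correlated at 0.834, and within CI-13 at 0.901. No pair of libraries within a group agreed within counting noise, so none was taken for a repeat deposit of another.

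**Figure D1:**
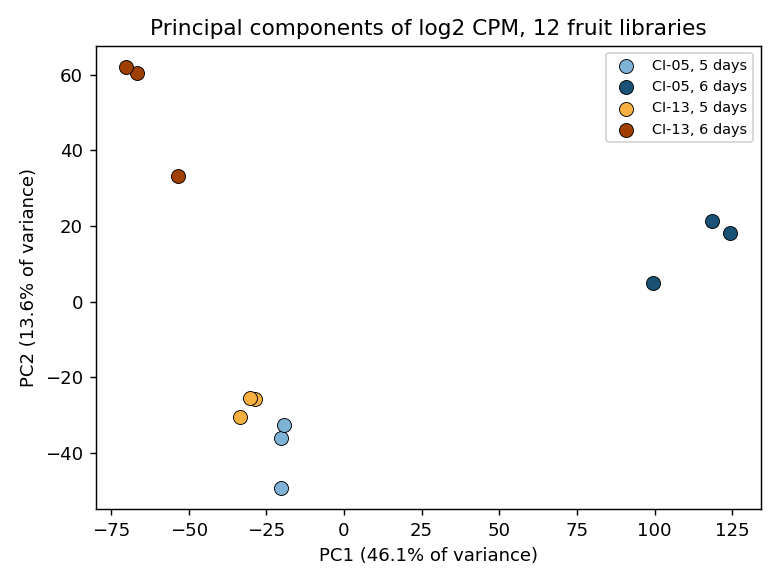
The 12 libraries on the first and second principal components of log2 CPM, coloured by genotype and day, 1 point per library. The 3 CI-05 libraries of 6 days lie at 99.5 to 124.4 on the first component, and the other 9 lie at -19.4 or below.

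Of the 10 most abundant genes, 4 differed between the genotypes at 5 days, 6 at 6 days and 7 in their day effects. The 3 described here were chosen after their values were seen. GWHTBFSC009529 was among the most abundant in CI-05, at 33902 ± 283 CPM at 5 days and 29343 ± 4880 at 6 days, and reached only 213 ± 9 and 362 ± 33 CPM in CI-13 (SD, n = 3 each). It was 159-fold higher in CI-05 at 5 days (log2 -7.31 for CI-13 against CI-05, SE 0.19, edgeR quasi-likelihood adjusted p = 2.41e-09). At 6 days it was 81.1-fold higher (log2 -6.34, SE 0.18, edgeR quasi-likelihood adjusted p = 3.72e-09), with no overlap of libraries on either day. GWHTBFSC012380 fell in CI-05 from 31703 ± 689 to 17429 ± 518 CPM and rose in CI-13 from 36967 ± 5163 to 58170 ± 1771 CPM (SD, n = 3 each). Its genotype difference was not called at 5 days (log2 0.22, SE 0.13, edgeR quasi-likelihood adjusted p = 0.311). At 6 days it was 3.34-fold higher in CI-13 (log2 1.74, SE 0.14, edgeR quasi-likelihood adjusted p = 1.45e-06). GWHTBFSC021708 was likewise 3.48-fold higher in CI-13 at 6 days (log2 1.8, edgeR quasi-likelihood adjusted p = 1.96e-06). The day effects of GWHTBFSC012380 differed by 1.52 on the log2 scale (SE 0.19, edgeR quasi-likelihood adjusted p = 9.4e-05). The 10 most abundant genes of a library held 13.73 ± 0.12% of counts in CI-05 at 5 days and 10.33 ± 0.46% at 6 days. In CI-13 they held 12.07 ± 0.76% and 15.63 ± 0.4% (SD, n = 3).

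**Figure D2:**
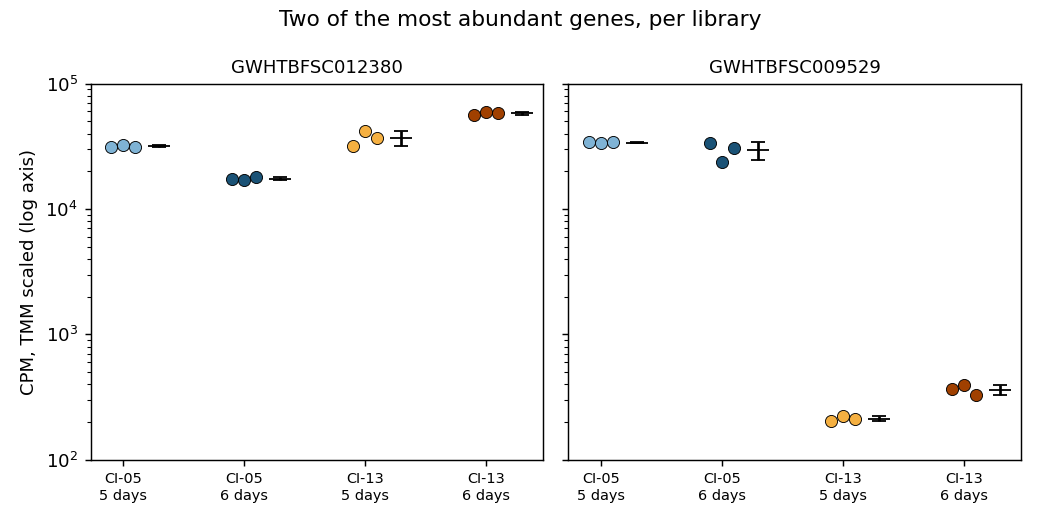
TMM-scaled CPM on a log axis for GWHTBFSC012380 and GWHTBFSC009529 in the 4 groups, 1 point per library, with the mean and SD of 3 libraries beside the points. GWHTBFSC009529 lies near 213 to 362 CPM in CI-13 and near 29343 to 33902 in CI-05, and GWHTBFSC012380 moves in opposite directions from 5 to 6 days.

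The genotypes differed in fewer genes at 5 than at 6 days. At 5 days CI-13 was higher than CI-05 in 836 genes and lower in 935, together 12.1% of the 14664 tested. The median change of the called genes was 2.02-fold among the higher and 1.91-fold among the lower, and 424 and 429 of them changed at least 2-fold. GWHTBFSC020902 averaged 47.8 ± 2.51 CPM in CI-13 and was at 0 in all 3 CI-05 libraries, so it was at least 367-fold higher in CI-13 (edgeR quasi-likelihood adjusted p = 0.0176). In CI-13 at 6 days it was at 0 in replicate 3 and at 33.5 and 27.1 CPM in the other libraries. It is thus 1 of 456 genes that switched between replicates of a group, and its 0 in CI-05 is uncertain. GWHTBFSC013843 reached 1180 ± 743 CPM in CI-13 against 2 ± 0.0315 in CI-05, a ratio of means of 590 (edgeR quasi-likelihood adjusted p = 0.0161). Its CI-13 libraries ran from 450 to 1930 CPM, each above every CI-05 library of 5 days. In CI-05 at 6 days it was at 1250 CPM in replicate 3 and at 3.87 and 3.47 in the other libraries, so its low level in CI-05 is uncertain too. GWHTBFSC001775 was detected in CI-05 at 5 days at 13.8 ± 9.49 CPM and in no library of the other 3 groups, and was at least 95.8-fold lower in CI-13 (edgeR quasi-likelihood adjusted p = 0.00709), or at least 58.2-fold without CI-05 replicate 2. GWHTBFSC017696 was listed at 11.4 ± 2.16 CPM in CI-05 and at 0 in CI-13 (edgeR quasi-likelihood adjusted p = 0.0054). Between replicates, GWHTBFSC017697 mirrored the sum of it and GWHTBFSC017695 (r = -0.89 of deviations from group means), so the value is uncertain. GWHTBFSC017696 itself correlated with the sum of its neighbours at r = -0.76, short of the limit of -0.8. Summed with GWHTBFSC017695 and GWHTBFSC017697 it averaged 17.1 ± 0.989 CPM in CI-05 and 21.4 ± 1.3 in CI-13 (log2 0.32, edgeR quasi-likelihood adjusted p = 0.16), so no difference was called.

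The calls at 5 days depended on single libraries. Without CI-05 replicate 1 of 5 days, 313 genes were higher and 401 lower, and without replicate 2, 322 and 435. Without replicate 3 they were 724 and 828. By chi-square per degree of freedom over genes, replicates 1 and 2 of this group differed by 4.67. Replicate 3 differed from them by 15.35 and 16.34. Without CI-13 replicate 1 of 5 days they were 472 and 528, and without replicate 2, 466 and 557. The call of GWHTBFSC020902 was lost without CI-05 replicate 1 (adjusted p = 0.0598) or 2 (0.0569), and that of GWHTBFSC013843 without replicate 1 (0.0775), 2 (0.0749) or 3 (0.0513), all by edgeR. With DESeq2 the adjusted p of GWHTBFSC001775 was 0.146, the highest of a range from 0.00342 over its alternatives. With library totals in place of TMM factors, 60.9% of the calls were higher against 47.2% with TMM, and the median of all genes shifted to 0.09.

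At 6 days the genotypes differed in 43.5% of the tested genes, with 3073 higher and 3308 lower in CI-13. The median change was 2.06-fold among the higher and 2.97-fold among the lower, and 1601 and 2310 changed at least 2-fold. GWHTBFSC018012 averaged 162 ± 40.3 CPM in CI-13 against 0.0568 ± 0.0983 in CI-05, where 1 count was seen in all. The ratio of summed counts, scaled by the effective library totals, was 2540 (95% counting interval 456 to 1e+05; edgeR quasi-likelihood adjusted p = 9.93e-06). It was also higher in CI-13 at 5 days, at 124 ± 61.6 CPM against 3.49 ± 4.2 (edgeR quasi-likelihood adjusted p = 0.000854). GWHTBFSC006611 was at 0 in all 6 CI-05 libraries and averaged 16.7 ± 6.7 CPM in CI-13 at 6 days, at least 87.1-fold higher (edgeR quasi-likelihood adjusted p = 2.56e-05). GWHTBFSC020268 averaged 83.5 ± 18.6 CPM in CI-05 at 6 days and was at 0 in the 3 CI-13 libraries, at least 536-fold lower in CI-13 (edgeR quasi-likelihood adjusted p = 3.2e-06). It was under 1 CPM in every library of 5 days. GWHTBFSC002173 was listed at 82.8 ± 25.2 CPM in CI-05 and at 0 in CI-13 (edgeR quasi-likelihood adjusted p = 0.0025). Its counts correlated with the sum of its neighbours at r = -0.6 within groups, short of the limit of -0.8 set for mirroring, and the neighbours were chosen by hand after their values were seen. Summed with GWHTBFSC002171 and GWHTBFSC002172, it averaged 97.4 ± 22.3 CPM in CI-05 and 30.7 ± 2.58 in CI-13 (log2 -1.67). No p is given for this sum, because a sum picked for a low spread within groups favours a call.

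Genes on in 1 genotype and off in the other at 6 days, a class defined after the data were seen, were mostly on in CI-05. With at least 5 CPM in each library of the first and at most 3 counts in all of the second, 60 genes were on in CI-05 and off in CI-13, and 7 were the reverse. The 60 include GWHTBFSC002173, whose 0 in CI-13 is uncertain, since its sum with its neighbours averaged 30.7 CPM there. The genotype effects of the days were weakly related. Of the genes called on both days, 589 had the same direction and 481 the opposite, against 386 and 385 for independent lists. Shared calls exceeded that number in both classes and more so in the same direction. Genes with a low spread are called more readily on both days, so an excess in both classes does not by itself show a shared effect. Fold changes on the days, which shared no library, correlated across genes at r = 0.09 (Spearman rho 0.06), and genes are not independent replicates. Without CI-05 replicate 1 of 5 days the shared calls were 277 and 175, and without replicate 2, 294 and 180. Without replicate 3 they were 488 and 489, so the larger number in the same direction rested on that library. Without CI-13 replicate 1 of 5 days they were 353 and 253, and without replicate 2, 360 and 277. With library totals in place of TMM, 4634 genes were higher and 64.1% of the calls were higher, against 48.2% with TMM, and the median of all genes shifted to 0.28.

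**Figure D3:**
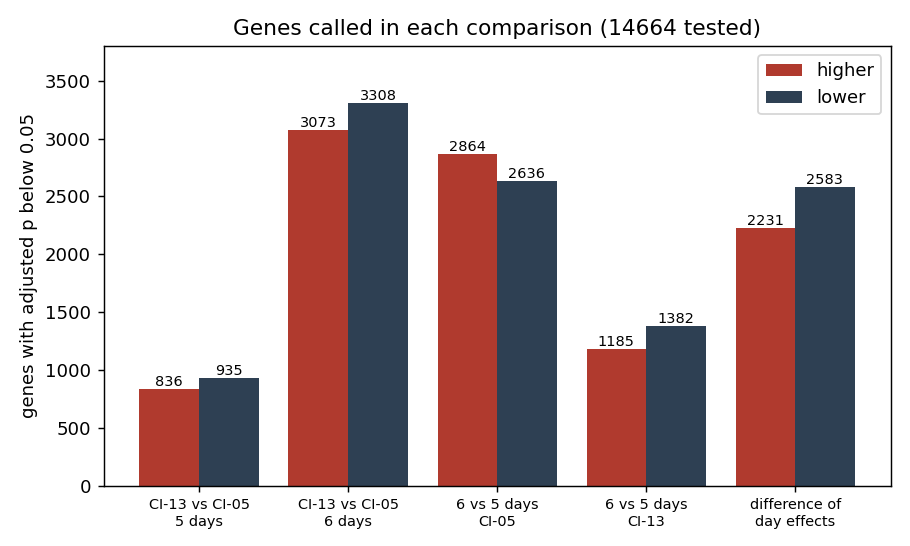
Genes called higher and lower (adjusted p under 0.05 of 14664 tested) in each comparison, with the interaction as the difference of day effects. The bars at 6 days, 3073 and 3308, exceed those at 5 days, 836 and 935, and CI-05 has more calls between the days than CI-13.

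From 5 to 6 days, CI-05 fruit changed in 37.5% of the tested genes, with 2864 higher and 2636 lower at 6 days. Genes that rose held 19.1 ± 0.4% of all counts at 5 days and 47.5 ± 5.1% at 6 days, and those that fell went from 32.8 ± 1.1% to 13.2 ± 1.9% (SD, n = 3 each). The same genes held 21.9 ± 0.6% and 30.7 ± 0.7% of the counts of CI-13 at 5 days. At 6 days in CI-13 they held 19.6% and 34.9%, with SDs of at most 0.4 points. The median rise was 2.5-fold and the median fall 1.96-fold, and 1823 genes rose and 1269 fell at least 2-fold. GWHTBFSC017062 was at 0 in the 3 libraries of 5 days and averaged 45.4 ± 3.2 CPM at 6 days, at least 349-fold higher (edgeR quasi-likelihood adjusted p = 3.03e-06). In CI-13 it had at most 3 counts in any library. GWHTBFSC002173 was listed at 0 at 5 days (edgeR quasi-likelihood adjusted p = 0.00271). Summed with its neighbours it went from 28.3 ± 2.73 to 97.4 ± 22.3 CPM (log2 1.78). GWHTBFSC000542 averaged 19.4 ± 22.4 CPM at 5 days and was at 0 in the libraries of 6 days, at least 102-fold lower (edgeR quasi-likelihood adjusted p = 0.00587). That limit rests on replicate 3 of 5 days at 45 CPM, and without it the fall was at least 34.8-fold. In CI-13 it fell from 125 ± 48.3 to 6.25 ± 5.32 CPM (edgeR quasi-likelihood adjusted p = 0.00929). GWHTBFSC001775 was at least 72.1-fold lower at 6 days (edgeR quasi-likelihood adjusted p = 0.00187), or at least 43.8-fold without replicate 2 of 5 days. With DESeq2 the adjusted p was 0.109, the highest of a range from 0.000682 over its alternatives. With library totals in place of TMM, 4532 genes were lower and 30.7% of the calls were higher, against 52.1% with TMM, and the median of all genes shifted to -0.33.

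In CI-13 fewer genes changed between the days, 1185 higher and 1382 lower at 6 days, or 17.5% of those tested. Genes that rose went from 19.1 ± 0.1% to 33.6 ± 0.9% of the counts, and those that fell from 16.1 ± 1.1% to 5.7 ± 0.4% (SD, n = 3 each). The median rise was 1.78-fold and the median fall 2.4-fold, and 415 genes rose and 878 fell at least 2-fold. GWHTBFSC014709 averaged 26.6 ± 13.6 CPM at 5 days and had 1 count in all at 6 days, a ratio of scaled summed counts of 498 (95% counting interval 89.1 to 19700; edgeR quasi-likelihood adjusted p = 9.96e-05). GWHTBFSC004367 went from 5.89 ± 4.66 CPM to 0 in all 3 libraries, at least 37.8-fold lower (edgeR quasi-likelihood adjusted p = 0.00245). Without replicate 1 of 5 days, at 11.1 CPM, it was at least 20.9-fold lower. GWHTBFSC022701 was at 0 at 5 days and averaged 20.6 ± 5.46 CPM at 6 days, at least 143-fold higher (edgeR quasi-likelihood adjusted p = 0.0413). It was at 0 in 1 CI-05 library of each day and at 8.57 to 40.4 CPM in the others, and its call was lost without any 1 of the 6 CI-13 libraries (edgeR adjusted p from 0.0563 to 0.1), without CI-05 replicate 1 or 3 of 5 days (0.0554 and 0.0575) or without CI-05 replicate 2 of 6 days (0.0538). GWHTBFSC017696 was listed as higher at 6 days (edgeR quasi-likelihood adjusted p = 0.00349), but summed with its neighbours it averaged 21.4 ± 1.3 and 21.1 ± 3.03 CPM (log2 -0.02, edgeR quasi-likelihood adjusted p = 0.954). Without CI-13 replicate 2 of 6 days, 681 genes were higher and 848 lower. Without CI-13 replicate 1 of 5 days 733 were higher, and without replicate 2, 777. With library totals in place of TMM, 764 genes were higher and 29.3% of the calls were higher, against 46.2% with TMM, and the median of all genes shifted to -0.13.

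The change between the days differed between the genotypes. The interaction was called in 4814 genes, 32.8% of those tested, of which 2231 had the more positive change in CI-13 and 2583 the more positive change in CI-05. With library totals in place of TMM these were 2836 and 2210, so 56.2% of the calls lay toward CI-13 against 46.3% with TMM, and the median of all genes shifted to 0.2. Of the 4814, 923 (19.2%) were called in opposite directions, 2653 (55.1%) were called in CI-05 alone and 750 (15.6%) in CI-13 alone. A further 85 (1.8%) were called in the same direction and 403 (8.4%) in neither genotype. The opposite group held 526 genes that rose in CI-05 and fell in CI-13, and 397 that fell in CI-05 and rose in CI-13. Over all genes called between the days in both genotypes, 440 had the same direction and 923 the opposite, against 480 and 483 for independent lists. Of the 2864 genes that rose in CI-05, 2028 (70.8%) had a called interaction, and 203 rose and 526 fell in CI-13. Of the 2636 that fell in CI-05, 1633 (61.9%) had a called interaction, and 237 fell and 397 rose in CI-13. The interaction contains the CI-05 day difference by which these genes were chosen. That choice alone raises both shares above the 32.8% of all tested genes, so no conclusion is drawn from the shares. Only the calls in CI-13 come from other libraries. Fold changes between the days correlated across genes at r = -0.15 between the genotypes (Spearman rho -0.12), which shared no library.

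Among single genes, GWHTBFSC022319 fell in CI-05 from 38.8 ± 23.7 to 0.85 ± 0.358 CPM and rose in CI-13 from 40 ± 18.3 to 611 ± 128 CPM (interaction log2 9.45, SE 0.82, edgeR quasi-likelihood adjusted p = 7.97e-06). GWHTBFSC017696, GWHTBFSC002173 and GWHTBFSC021033 also ranked among the largest interactions, but each had at least 1 group at 0. Summed with the neighbours chosen by hand, GWHTBFSC002173 had an interaction of -1.22 on the log2 scale. Summed likewise with their neighbours, GWHTBFSC017696 (log2 0.08, edgeR quasi-likelihood adjusted p = 0.797) and GWHTBFSC021033 (log2 -0.13, edgeR quasi-likelihood adjusted p = 0.759) had no called interaction. The call of GWHTBFSC021033 was also lost without any 1 of 9 of the 12 libraries, with edgeR adjusted p up to 1 without CI-13 replicate 2 of 5 days. Without CI-13 replicate 2 of 6 days, 263 genes were called between the days in the same direction in both genotypes and 583 in opposite directions. Without CI-13 replicate 1 of 5 days, 277 were called in the same direction.

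**Figure D4:**
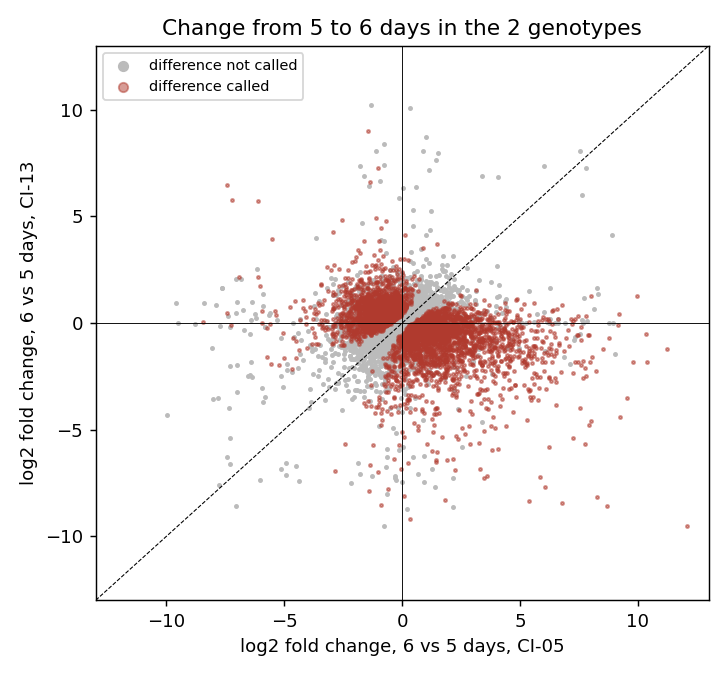
Log2 fold change from 5 to 6 days in CI-05 (horizontal) against CI-13 (vertical), 1 point per tested gene, with called interactions in red and the dashed line marking equal change. The 4814 called genes lie away from that line, and 923 of them were called in opposite directions.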

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

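The tests of other groupings, of abundant genes and of depth were chosen before their results were seen. The tests of RNA from another source, of GWHTBFSC009529 and of genes that switched between replicates were chosen afterwards. The test of another source was run before in 2 other forms, which were dropped because they rested on genes selected for their change.

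The change from 5 to 6 days differed between the genotypes in 2231 genes toward CI-13 and 2583 toward CI-05, by the test of the interaction itself. Without the 100 most abundant genes 4738 interaction calls were made. TMM factors already trim the most abundant genes, so this test could hardly turn out otherwise and decides nothing about the scaling. Unequal depth is argued against as the source, since 4713 calls were made after thinning all libraries to the smallest. Neither test covers a shift in the counts spread over many genes. RNA of another source at most 50% of the counts cannot lower a gene's share below 50% of its former value. Tested against a 2-fold change in share, 698 of 14664 genes fell further in CI-05 and 854 rose further (570 and 820 of them with a called interaction). For these genes, the falls argue against such a source at 6 days alone as the only cause, and the rises against one at 5 days alone. Such a source beside a response of the fruit, or behind the other called interactions, stays open. A source in the CI-13 libraries was not tested. A source above 50%, or different sources on both days, cannot be told apart from a response of the fruit, because 0 identifiers had a name by which markers could be tested. A difference in response, in ripening or in the progress of the rot between the genotypes was not tested and stays open.

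Other groupings of the libraries were tried for each comparison. For the interaction, 1 of 50 groupings of the day labels within genotypes gave as many calls, the real one with 4814, and the highest other gave 2242. Such groupings also remove the day effects themselves and add them to the spread within groups, which lowers the calls. They therefore do not test for the absence of an interaction, and no conclusion is drawn from them. The other comparisons have only 10 splits each, too few for a share under 0.05, and in each only 1, the real split, reached its own count. The real splits called 1771 genes between genotypes at 5 days, 6381 at 6 days, 5500 between days in CI-05 and 2567 in CI-13. The highest of the other splits called 1, 1, 1 and 3 genes. Those splits mix libraries of both groups, so a difference between the groups enters the spread within groups and lowers the calls. No conclusion is drawn from them either.

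GWHTBFSC009529 was nearly missing in CI-13. It was 1 of 7 among the 10 most abundant genes with a called interaction. Its day effects differed between the genotypes by 0.97 on the log2 scale (edgeR adjusted p = 0.00377). Assignment of its reads to 1 near-identical copy in CI-13 is argued against at 5 days. It lacked 33687 CPM there at 5 days, and the largest gain of any gene was 7600 CPM, by GWHTBFSC009329. Reads spread over several copies are not covered, and 6 days was not tested. At 6 days GWHTBFSC009529 averaged 362 CPM in CI-13 against 29343 in CI-05, and GWHTBFSC012380 averaged 58170 against 17429. The same comparison would therefore not argue against 1 copy on that day. Sequence differences of CI-13 from the reference, which could keep reads from being assigned, cannot be told apart from a true difference in expression, because a day effect that differs by 0.97 fits either. A genetic difference between the genotypes in the expression of this gene stays open as well.

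Many genes switched on and off between replicates of 1 group. At 0 in 1 library and at 5 CPM or more in another of the same group were 456 tested genes, while at most 1 was found in 100 sets of counts drawn with the common dispersion, which argues against counting noise. In 195 of them neighbouring identifiers mirrored the switch, against at most 28 in 1000 draws of random identifiers. Reads assigned in turn to different near-identical neighbours are therefore a candidate explanation for these 195. Whether such neighbours are separate genes or transcripts of the same gene was not checked, because the annotation was not given. A first search with single neighbours, 10 CPM and a correlation of -0.6 found 151 of 215, against at most 60. For the other 261 a near-identical gene elsewhere and a true difference between samples cannot be told apart without the transcript sequences.

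A further 10 genes had a called interaction. GWHTBFSC002173 differed by -21.63, GWHTBFSC021033 by -17.28, GWHTBFSC020268 by -12.6, GWHTBFSC017062 by -12.42 and GWHTBFSC004367 by -10.11 on the log2 scale. GWHTBFSC014709 differed by -7.66, GWHTBFSC018012 by 5.74, GWHTBFSC022319 by 9.45, GWHTBFSC017696 by 10.48 and GWHTBFSC012380 by 1.52. Fitted values of genes with a group at 0, the first 5 and GWHTBFSC017696 among them, depend on the prior count and are no bounds. With mirroring neighbours summed, the interactions of GWHTBFSC021033 (log2 -0.13, edgeR adjusted p = 0.759) and GWHTBFSC017696 (0.08, 0.797) were not called, and that of GWHTBFSC002173, with neighbours chosen by hand, shrank to -1.22.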

How the results depend on the processing

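Library totals alone, the left-out abundant genes, the thinning and the summed neighbours were added after the data were seen. All counts of calls stayed within 1.5 times their value under median-of-ratios factors, DESeq2, both count filters, the thinning, the left-out abundant genes and the summed neighbours. Those of the 4 comparisons between single groups also did so in the fit of only the groups compared, which gives no interaction, since that needs all 4 groups. With library totals alone, 4634 genes were higher in CI-13 at 6 days, 4532 were lower at 6 days in CI-05, and 764 were higher at 6 days in CI-13, since that setting leaves out the TMM factors. These were 1.031 to 1.059 in CI-05 at 5 days, 0.819 to 0.904 in CI-05 at 6 days, 1.097 to 1.132 in CI-13 at 5 days and 1.003 to 1.025 in CI-13 at 6 days. With 1 library left out, genes higher and lower in CI-13 at 5 days ranged from 313 to 868 and from 401 to 1056. Genes that rose and fell in CI-13 ranged from 681 to 1321 and from 848 to 1421. Shared genotype calls ranged from 277 to 647 and opposite ones from 175 to 500. Shared day calls ranged from 263 to 519 and opposite ones from 583 to 923. The smaller number of libraries alone does not account for the range at 5 days. Without CI-05 replicate 1, 2 or 3 of 5 days, the genes higher in CI-13 were 313, 322 and 724. Causes were not tested further. The other counts stayed within 1.5 times. Over the alternatives, values of named genes were past the threshold in the same direction 396 times, not past it 29 times and reversed 2 times. Both reversals were GWHTBFSC017696 with neighbours summed, at 0.32 between genotypes at 5 days and -0.02 between days in CI-13. Whether reads moved between these neighbours cannot be told without the transcript sequences.

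Replicate numbers did not pair the libraries. Deviations from the group means of same-numbered libraries correlated at -0.07 to 0.07 in 18 pairs, with 0 above 0.1, and 2 of 12 libraries correlated best with their own number. With the replicate number as a block, calls higher and lower were 682 and 770 between genotypes at 5 days, 2878 and 3194 at 6 days, 2711 and 2461 between days in CI-05, 972 and 1195 in CI-13, and 2043 and 2424 for the interaction. The calls of GWHTBFSC022701 between days in CI-13 (adjusted p = 0.0644) and of GWHTBFSC021033 for the interaction (0.0558) were not made with the block. The planned tests of gene lists and their alternatives were not run, because no identifier had a name, and library sizes with fungal counts did not apply. Depth limits genes near the group limits of 0.13 to 0.191 CPM.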

Other observations

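The tests of neighbouring identifiers and the classes in this part were chosen after the data were seen. Genes with large differences between the genotypes on both days were about evenly divided. Called on both days and over 8-fold apart on each were 25 genes higher in CI-13 and 28 higher in CI-05. At 6 days against 5 days in CI-05, 17 genes went from at most 3 counts in the group to at least 5 CPM in every library, and 2 did the reverse. In CI-13, 3 genes did so in each direction. GWHTBFSC002173 was among the 17, and GWHTBFSC017696 and GWHTBFSC022701 were among those that rose in CI-13, so some of these low groups are uncertain.

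Fold changes of genes with consecutive identifiers were weakly correlated. Over 9567 consecutive pairs of tested identifiers, fold changes correlated at a Spearman rho of 0.19 between the days in CI-05 and of 0.1 in CI-13. Between the genotypes rho was 0.07 at 5 days and 0.17 at 6 days, and for the interaction it was 0.17. The highest of 1000 shuffles was 0.035 over the 5 comparisons, and pairs 100 genes apart had rho between -0.02 and 0.01. The permutation p was 0.001 in each, the smallest that 1000 shuffles can give as rounded here.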
